A study of Mus musculus with 9 samples.

How the data were processed

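The data were 9 arrays of ventricular RNA, 3 each from IGF1R, IGF1R-caPI3K and IGF1R-dnPI3K mice, with groups taken from the sample titles. The titles also give a mouse number, and each number belongs to 1 mouse. Replicates were numbered in deposit order, which pairs no samples. The deposited table holds 1 intensity per probe set and array on a linear scale, for 12488 probe sets, of which 66 are controls. The values show that each array had been scaled to a common 2% trimmed mean. The algorithm, its version and any detection calls are not given in the sources used here, so the scale of the intensity rests on the deposited values alone.

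Array precision is limited by the number of arrays. No 2 arrays held the same values: 18 to 29 probe sets were identical within pairs of a group. Y-linked probe sets had signals of at most 47.4 and were not tested. The limma p-values of probe sets measure the spread between the mice within groups, estimated over all 3 groups together. Those of camera set a list's genes against the other genes at a preset correlation, and a permutation over genes takes genes as independent. Neither of these stands for the spread between mice alone.

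Gene symbols came from the platform annotation given with the table: 10833 probe sets had 1 symbol, 396 had several and 1193 had none, and no gene was named from a probe set with several. Of those with 1 symbol, 10817 had an identifier in the RefSeq gene table, and 0 symbols changed on updating. The genome build behind the annotation is not given in the sources used here, and no coordinates were used.

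Control probe sets were left out of the tests. Values were kept on the deposited scale, raised to a floor of 32.4, the 20th percentile of positive values over all arrays, and taken to log2. Probe sets above the 40th percentile of their array on at least 3 arrays were kept, which left 7898. Values at or below the floor made up 0.346% of those tested. All 9 arrays entered one linear model in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with moderated variances that follow the mean signal, so that the 3 groups share an estimate of spread. The 3 pairwise contrasts and an F test were adjusted by Benjamini-Hochberg, each over all probe sets tested, with a threshold of 0.05. Signals are given as mean ± SD of the deposited values and log2 fold changes as estimate ± SE.

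Gene lists were tested with camera at a preset correlation of 0.01 over 1 probe set per gene, the one with the highest mean. Of 33 lists, 31 had at least 5 measured genes; the red blood cell list had 4 and the list that checks sex had 1. Of 728 list entries 2 matched no symbol. Camera compares a list with the other genes, while fry, an alternative, tests whether a list's genes move one way. Camera with a correlation estimated for each list passed none of the lists in any comparison (lowest adjusted p 0.959, 0.573 and 0.188).

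The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule took, for each comparison, up to 12 genes in each direction with the largest change among those that passed and whose groups did not overlap, or, with under 5, the 5 with the lowest p. It added up to 4 genes of each list that passed or held a passing gene, and a fixed set of transgene and cardiac stress genes. The text leaves out some genes that the rule names. The rule did not say whether the largest changes were to be sought among all probe sets of a gene or only the one with the highest mean. The second reading was chosen after values had been seen, and leaves out larger changes on dimmer probe sets, such as that of Hus1.

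Alternatives were quantile normalization, scaling to a common median, 3 other treatments of low values, other filters, other variance models, array weights, the mouse number series as a block, fits with only the 2 groups compared, each array left out in turn and other set tests. Another 3 alternatives were added after seeing the data: leaving out probe sets whose names mark possible shared targets, and quantile normalization together with only the 2 groups compared or without IGF1R-dnPI3K replicate 3. The band of 0.1 within which a correlation counts as kept was a choice made here.

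The model was tested on simulated data drawn from the real means and spread. With 200 of 7898 probe sets changed between IGF1R-dnPI3K and IGF1R arrays, it recovered 13.3% of changes of 0.5 on the log2 scale, 68.1% of changes of 1 and 95.5% of changes of 2. False calls made up 5.29% of the calls. The real IGF1R-dnPI3K arrays spread more than the others (median SD of log2 signal 0.26 against 0.16), so these rates need not hold for the real comparisons.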

Results

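RNA from both ventricles of the heart was measured in 9 female mice aged 3 months, with 1 array per mouse. All mice carried a transgene for the insulin-like growth factor 1 receptor (IGF1R). In 3 mice it was the only transgene (the IGF1R group). In 3 mice it was combined with a constitutively active form of the lipid kinase PI3K (IGF1R-caPI3K), and in 3 with a dominant negative form (IGF1R-dnPI3K). Mice with a PI3K transgene alone and mice without a transgene are named in the labels and were not analysed here, so no value below is relative to a normal heart. The median deposited signal per array ran from 161 to 197, and the number of arrays limits the precision.

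The arrays differed in ways that ran with the groups. The ratio of 3' to 5' signal of the CreX hybridisation control, which is added to each sample during processing, was 1.18 ± 0.11 (SD, n = 3) on the IGF1R arrays. It was 1.80 ± 0.08 (SD, n = 3) on the IGF1R-caPI3K arrays and 1.81 ± 0.02 (SD, n = 3) on the IGF1R-dnPI3K arrays. The 3' to 5' ratio of Gapdh, which comes from the RNA of the sample itself, was 0.747 to 0.818 on the IGF1R arrays and 0.843 to 0.943 on the other 6. Among the IGF1R-dnPI3K arrays, that of replicate 3 stood apart, with a mean Pearson correlation to the other arrays of 0.927 across probe sets, against 0.947 to 0.956 on the other 8 arrays. Its 3' to 5' ratio of pyruvate carboxylase was 3.25, against 1.40 to 2.11 on the others. The first principal component held 38.4% of the variance and the second 14.3%. The median SD of log2 signal between mice was 0.26 in the IGF1R-dnPI3K group, 0.16 in the IGF1R group and 0.16 in the IGF1R-caPI3K group.

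**Figure D1:**
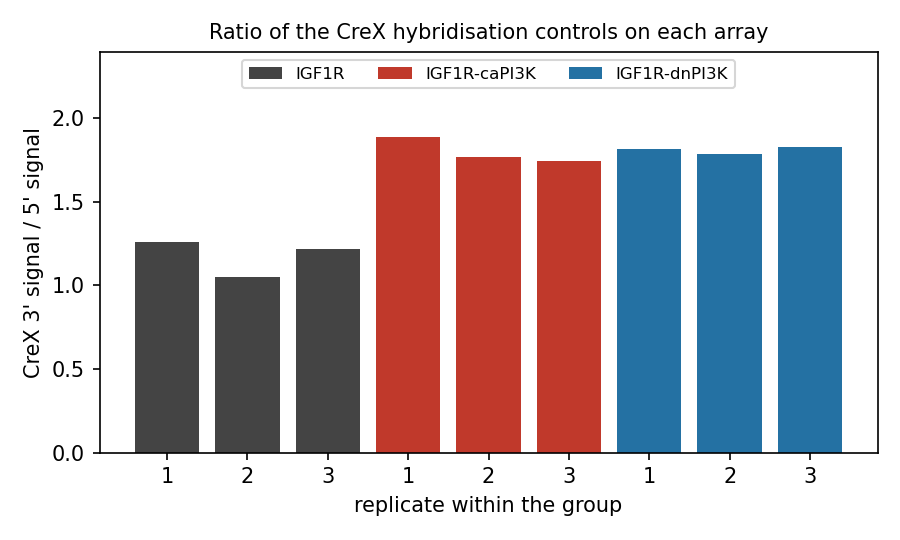
Ratio of the 3' to the 5' signal of the CreX hybridisation control (vertical axis, no unit) on each of the 9 arrays, coloured by group, with the replicate number below. The 3 IGF1R arrays lie between 1.05 and 1.26 and the other 6 between 1.74 and 1.89.

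The genes behind the transgenes were examined first. The signal of Igf1r, the receptor for insulin-like growth factor 1, was 903 ± 72.3 (SD, n = 3) in IGF1R mice, 1138 ± 182 (SD, n = 3) in IGF1R-caPI3K mice and 1772 ± 178 (SD, n = 3) in IGF1R-dnPI3K mice. It was higher in IGF1R-dnPI3K than in IGF1R mice by 0.97 ± 0.14 on the log2 scale (SE, limma adjusted p = 0.00827). The difference between IGF1R-caPI3K and IGF1R-dnPI3K mice, -0.65 ± 0.14, did not pass (adjusted p = 0.0582). Pik3ca, which encodes a catalytic subunit of PI3K, and Pik3r1, which encodes a regulatory subunit, passed in none of the 3 comparisons. Whether these probe sets match the transgenes is not given in the sources used here, so they do not check the labels.

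The effect of adding active PI3K to the IGF1R transgene was read from IGF1R-caPI3K against IGF1R mice. Among genes read from their brightest probe set, the largest rise was that of Txnrd3, a thioredoxin reductase, from 216 ± 56.1 to 1045 ± 353 (SD, n = 3 each), a log2 change of 2.26 ± 0.24 (SE, adjusted p = 0.0132). Cela1, a serine protease, rose by 1.39 ± 0.23, and Chad, a cartilage matrix protein, by 1.20 ± 0.20 (adjusted p = 0.0482 for both). Smaller rises passed for the chaperone cofactor Bag2 (0.85 ± 0.13), Atp6v0e2 (0.83 ± 0.12), the transcriptional corepressor Trim28 (0.82 ± 0.12), Krtcap2 (0.76 ± 0.12) and Lsm14b (0.69 ± 0.11). The other probe sets of Bag2 and Krtcap2, at 0.218 and 0.401, did not pass. The B cell receptor component Cd79a fell from 287 ± 40.3 to 80.4 ± 3.08, a log2 change of -1.83 ± 0.22 (adjusted p = 0.0178). Ryr2, the calcium release channel of the sarcoplasmic reticulum, fell from 6946 ± 234 to 4274 ± 200, a log2 change of -0.70 ± 0.11 (adjusted p = 0.0464). Ckm, the muscle creatine kinase, differed by -0.59 ± 0.10 on its brightest probe set and by 0.788 on another, so its direction is open. The names of the probe sets read for Txnrd3, Bag2, Krtcap2 and Ckm mark possible shared targets, which could not be checked. Without all probe sets so named, 3 passed in this comparison instead of 17. Dimmer probe sets of 3 other genes also passed, named after their values were seen: Hus1 (26.9 ± 3.87 to 357 ± 37.0, a rise of open size, since Y-linked probe sets, which mark the background in these female mice, reached 47.4), Gnao1 (1.42 ± 0.23) and Flt3 (-0.93 ± 0.15). Their brightest probe sets, at -0.36 ± 0.32, 0.01 ± 0.14 and -0.06 ± 0.18, did not pass. The next lowest p among lower genes, none of which passed, belonged to Ell2 (-0.83 ± 0.15), Mtres1 (-0.88 ± 0.16), Cav3 (-0.78 ± 0.14), Fxr1 (-1.18 ± 0.21) and Fbxo8 (-1.08 ± 0.20); another probe set of Cav3 differed by 0.0291. The stress markers Nppa (0.35 ± 0.17), Nppb (0.25 ± 0.18), Acta1 (0.25 ± 0.19) and Myh7 (0.48 ± 0.27, its other probe set at -0.41) and the calcium pump gene Atp2a2 (-0.15 ± 0.09) did not pass.

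Among the gene lists, cell cycle and ribosomal protein genes lay higher in IGF1R-caPI3K than in IGF1R mice (camera, adjusted p = 0.0322 for both). Neither call held with an estimated correlation (adjusted p = 0.959 for both). Of 10 splits of these arrays into 3 and 3, the real one included, 8 shifted at least as many lists. The number of lists is thus no more than other splits give. After quantile normalization the median log2 change went from 0.30 to 0.33 for cell cycle genes and from 0.17 to 0.07 for ribosomal proteins. Among 10000 random lists matched on signal these medians, before that normalization, lay at the percentiles 99.99 and 91.8. Of 19 measured cell cycle genes 1 rose, and 2 did when adjusted over the list alone. The gene that rose was Cdk4, a kinase of the G1 phase, by 0.60 ± 0.10 (SE, adjusted p = 0.0482), while its other probe set differed by -0.0858. Values that did not pass were 0.70 ± 0.17 for Ccne1, 0.87 ± 0.28 for Mcm2 and 0.93 ± 0.33 for Ccna2. None of 23 ribosomal protein genes passed over all genes tested, and 3 rose when adjusted over the list alone; the lowest p belonged to Rpl41 (0.63 ± 0.16, adjusted p = 0.102). In calcium handling, 1 of 10 genes (Ryr2) fell, and in the lymphocyte markers 1 of 5 (Cd79a), with the same counts adjusted over the list alone for falls.

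In total, 17 of 7898 probe sets differed between IGF1R-caPI3K and IGF1R mice in limma at an adjusted p of 0.05, 12 higher and 5 lower, and 1451 had an unadjusted p under 0.05. The groups did not overlap in 32.8% of probe sets, against 10% by chance. The count rested on single arrays and on the IGF1R-dnPI3K arrays in the shared estimate of spread: it was 0 without IGF1R replicate 1, IGF1R replicate 2 or IGF1R-caPI3K replicate 3 (1111, 1134 and 1067 with an unadjusted p under 0.05), 1 without any of the other 3 arrays compared, 90 without IGF1R-dnPI3K replicate 1, 549 without IGF1R-dnPI3K replicate 3 (243 higher, 306 lower) and 699 with only the 6 arrays in the fit (310 higher, 389 lower). Because the CreX and Gapdh ratios separated the IGF1R arrays from the others, the group and a difference in RNA or array processing cannot be told apart in this comparison.

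Adding dominant negative PI3K was read from IGF1R-dnPI3K against IGF1R mice. Genes of the extracellular matrix fell: Postn, the matrix protein periostin, went from 3061 ± 470 to 1047 ± 815 (SD, n = 3 each), a log2 change of -1.80 ± 0.39 (SE, adjusted p = 0.0192). Col3a1, a fibrillar collagen, changed by -1.90 ± 0.50 (adjusted p = 0.0338), the collagen chaperone Serpinh1 by -1.16 ± 0.25 and Lum, the proteoglycan lumican, by -1.16 ± 0.21. The natriuretic peptide gene Nppa, a marker of cardiac stress, rose from 3077 ± 320 to 5430 ± 1227, by 0.80 ± 0.17 (adjusted p = 0.0185). Acta1, skeletal alpha-actin, which is expressed in fetal and overloaded hearts, fell from 16365 ± 852 to 10142 ± 3675, by 0.75 ± 0.19 on the log2 scale (adjusted p = 0.0325). Myl1, a light chain of skeletal myosin, fell from 6677 ± 545 to 1985 ± 565, a log2 change of -1.79 ± 0.19 (adjusted p = 0.00347). Nppb (-0.26 ± 0.18), Myh7 (0.24 ± 0.27, its other probe set at -0.71) and Atp2a2 (-0.05 ± 0.09) did not pass.

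Other large rises were those of Ptgds, which makes prostaglandin D (2.19 ± 0.40), the S6 kinase gene Rps6kb2 (2.18 ± 0.31), Txnrd3 (1.77 ± 0.24), Tspan4 (1.77 ± 0.26), the thioesterase Acot1 (1.67 ± 0.35) and Rdh13 (1.62 ± 0.38). Irs2, an adaptor of insulin receptor signalling, rose by 1.52 ± 0.38 and Gadd45b by 1.40 ± 0.35. The sizes for Irs2 (0.55 to 1.93 over the alternatives), Rdh13 (1.04 to 2.30) and Rps6kb2 (1.695 to 2.547) are open. Their signals in IGF1R mice, 62.1 ± 35.2, 85.5 ± 42.7 and 92.3 ± 44.6, reached down towards the background that Y-linked probe sets mark. The largest change among all probe sets tested was that of 1 probe set of Tbc1d10a, from 911 ± 293 to 12123 ± 2186, a log2 change of 3.77 ± 0.24 (limma adjusted p = 6.28e-05). The name of that probe set marks possible shared targets, which could not be checked. The gene's other probe set differed by -0.94 ± 0.70 and did not pass. Large falls also passed for Map6 (-2.08 ± 0.47), Mycn (-2.07 ± 0.50), the integrin Itga5 (-1.98 ± 0.27), Srpx (-1.91 ± 0.34), Dnajb9 (-1.84 ± 0.44), dystrophin (Dmd, -1.82 ± 0.39) and Maz (-1.70 ± 0.37). The sizes for Map6 (-2.49 to -0.91 over the alternatives), Mycn (-2.75 to -0.55) and Srpx (-2.38 to -0.97) are open. Their signals in IGF1R-dnPI3K mice, 53.8 ± 29.3, 77 ± 76.5 and 80.2 ± 50.2, reached down towards that background. Other genes had a group mean within that background, so the size of their change is open. Among these, the nuclear pore genes Nup188 (42.7 ± 5.02 to 173 ± 18.8) and Aaas (29.9 ± 7.42 to 135 ± 82.0) rose, and Kcne1l (166 ± 38.5 to 30.9 ± 11.8) and myostatin (Mstn, 152 ± 30.5 to 42.4 ± 10.5) fell; with a floor at the 40th percentile none of the 4 passed. A dimmer probe set of Arhgap9, named after its value was seen, rose from 25.6 ± 5.77 to 236 ± 76.6, while its brightest, at 0.72 ± 0.24, did not pass.

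Of 32 measured genes of extracellular matrix and fibroblasts, 9 fell and none rose (15 fell and 1 rose when adjusted over the list alone), with a median log2 change of -0.48 (camera adjusted p = 0.00496). Heat shock and chaperone genes also lay lower, with 4 of 14 falling (8 over the list alone; adjusted p = 0.00878), among them Hspa8 (-0.68 ± 0.13) and Hsp90aa1 (-0.70 ± 0.20). Macrophage and myeloid markers lay lower too (adjusted p = 0.0159): 3 of 16 fell (6 over the list alone), namely Csf1r (-0.71 ± 0.13), Lyz2 (-0.99 ± 0.20) and Mrc1 (-0.91 ± 0.24). With an estimated correlation the adjusted p was 0.573 for matrix and heat shock genes and 0.608 for myeloid markers. With the mouse number series as a block the direction of the myeloid list turned, but that fit sets IGF1R-dnPI3K replicate 1 alone against the IGF1R mice.

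Another 6 lists lay higher in IGF1R-dnPI3K than in IGF1R mice. Of 45 measured genes of oxidative phosphorylation 18 rose and 2 fell (24 and 4 over the list alone; camera adjusted p = 3.13e-07), among them Ndufa5 (0.82 ± 0.11), Ndufb7 (0.86 ± 0.14) and Atp5e (1.01 ± 0.18). Of 23 ribosomal protein genes 9 rose and 1 fell (13 and 1 over the list alone; adjusted p = 2.31e-05), including Rps18 (0.64 ± 0.12) and Rpl6 (0.71 ± 0.14). In the tricarboxylic acid cycle 5 of 17 rose and 1 fell (8 and 2 over the list alone; adjusted p = 0.00614): Idh2 rose by 0.91 ± 0.15 and Dld changed by -0.57 ± 0.15. In the proteasome list 5 of 30 rose (5 over the list alone; adjusted p = 0.00614), led by the activator subunit Psme1 (0.99 ± 0.11). In fatty acid oxidation 5 of 22 rose and 1 fell (9 and 1 over the list alone; adjusted p = 0.0197), including Eci1 (0.83 ± 0.17), Echs1 (0.62 ± 0.15) and Etfb (0.71 ± 0.13, with its other probe set at -0.217). Of 17 sarcomere genes 6 rose (7 rose and 1 fell over the list alone; adjusted p = 0.00496), including Myl2 (0.47 ± 0.12) and Tnnc1 (0.59 ± 0.15). With an estimated correlation the adjusted p of all 6 lists was 0.573. After quantile normalization none of the 6 passed and the sarcomere list turned to lower, as the sarcomere genes Myl3 and Myh6 also did.

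**Figure D2:**
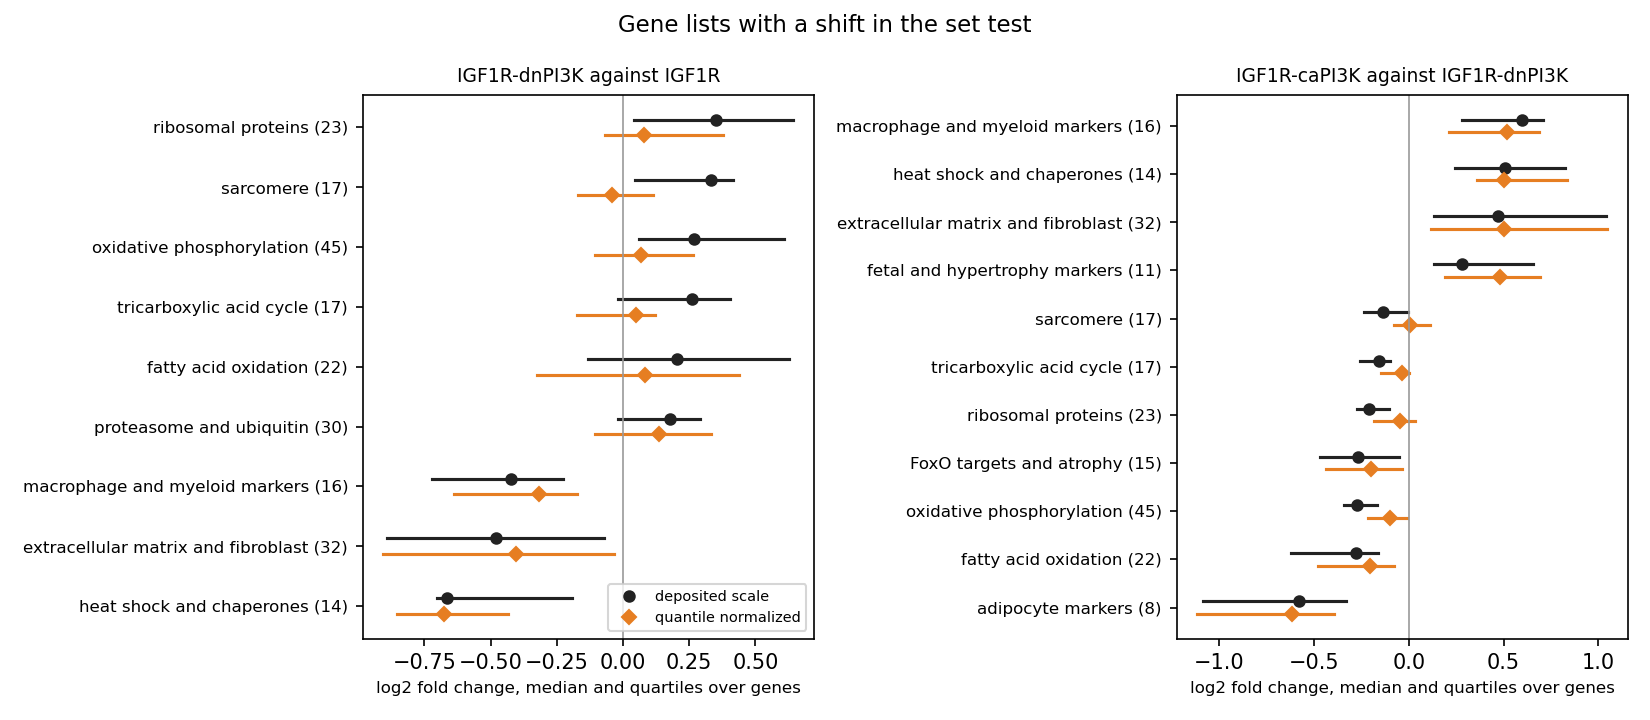
Median log2 fold change (point) and quartiles over genes (line) of each gene list that passed the set test, for IGF1R-dnPI3K against IGF1R (left) and IGF1R-caPI3K against IGF1R-dnPI3K (right), on the deposited scale (black) and after quantile normalization (orange), with the number of measured genes in brackets. The 6 lists that were higher in IGF1R-dnPI3K mice on the left lie nearer 0 after quantile normalization (sarcomere from 0.33 to -0.04), while the matrix list stays low (-0.48 and -0.40).

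Other lists had members that passed without a shift of the list. In insulin and Akt signalling 3 of 20 rose (3 over the list alone), namely Akt2 (0.92 ± 0.16), Irs2 and Gsk3a (0.44 ± 0.13). Among FoxO targets 4 of 15 rose and 2 fell (5 and 3 over the list alone), with Bcl2l11 at 0.87 ± 0.17, its other probe set at -0.507, and Cat at -0.92 ± 0.26. Among ion channels 2 of 13 rose and 1 fell (3 and 3 over the list alone): the potassium channel gene Kcna5 rose by 0.68 ± 0.15, Hcn2 by 0.56 ± 0.16 (its other probe set at 0.0751), and Kcnd2, a channel of the transient outward current, changed by -1.35 ± 0.23. Rcan1, a calcineurin target, fell with the fetal marker Acta1 (2 of 11 fell and 1 rose; 4 and 2 over the list alone), by 1.37 ± 0.33 on the log2 scale. Ryr2 changed by -0.55 ± 0.11 and S100a1 by 0.49 ± 0.14 in calcium handling (1 of 10 each way; 1 rose and 4 fell over the list alone). Among skeletal muscle markers 2 of 10 fell (Myl1 and Casq1, -1.31 ± 0.19) and Atp2a1 rose by 0.86 ± 0.25, with the same counts over the list alone. Among endothelial markers 3 of 17 rose and 2 fell (4 and 2 over the list alone), with Vwf at 0.63 ± 0.16 and Kdr at -1.16 ± 0.25. The mean signal of Kdr was 1308 in IGF1R, 702 in IGF1R-caPI3K and 614 in IGF1R-dnPI3K mice, so its fall is not particular to dominant negative PI3K.

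In total, 1066 of 7898 probe sets differed between IGF1R-dnPI3K and IGF1R mice (450 higher, 616 lower), and the groups did not overlap in 34.4% of probe sets, against 10% by chance. Without 1 array the count was 211, 200 or 77 (each IGF1R array in turn), 689 (IGF1R-caPI3K replicate 2), 1856 (IGF1R-dnPI3K replicate 1) and 653 (IGF1R-dnPI3K replicate 3). Scaling to a common median, which moved the median log2 change of all probe sets from -0.0944 to 0.0420, gave 735 higher and 396 lower. With only the arrays of the 2 groups compared in the fit, 132 passed (71 higher, 61 lower). The same kind of fit gave 699 for IGF1R-caPI3K against IGF1R. Which of these comparisons had more changes thus depends on the shared estimate of spread. With the mouse number series as a block this comparison rests on IGF1R-dnPI3K replicate 1, since the series of replicates 2 and 3 holds no other mouse. The group cannot be told apart from the difference in RNA or array processing that the CreX and Gapdh ratios mark.

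Active against dominant negative PI3K, both on the IGF1R background, was read from IGF1R-caPI3K against IGF1R-dnPI3K mice, whose arrays had alike CreX ratios. The 3' to 5' ratio of Actb, from the RNA of the sample, did separate them. It was 1.01 to 1.04 on the IGF1R-caPI3K arrays and 1.09 to 1.15 on the IGF1R-dnPI3K arrays. A difference in RNA is therefore not excluded between these groups either. In this comparison, higher or lower with active PI3K means against IGF1R-dnPI3K mice, not against IGF1R mice. Myl1 was higher with active PI3K, 10870 ± 925 against 1985 ± 565 (SD, n = 3 each), a log2 difference of 2.49 ± 0.19 (SE, adjusted p = 1.64e-04). Casq1, the skeletal calsequestrin, was 6875 ± 373 against 2139 ± 706, a difference of 1.73 ± 0.19 (adjusted p = 0.00241). Matrix genes were higher with active PI3K: Postn by 2.01 ± 0.39 (adjusted p = 0.037), Col1a1 by 1.78 ± 0.35 (adjusted p = 0.0387), Col5a2 by 1.62 ± 0.33 and Col8a1 by 0.79 ± 0.15. Each of these matrix genes passed in 10 of 24 alternatives. The inducible heat shock protein genes Hspa1a (2.50 ± 0.41, adjusted p = 0.0188) and Hspa1b (2.23 ± 0.46) and the cochaperone Hsph1 (1.19 ± 0.22) were also higher. The signal of Hspa1a was 703, 624 and 2146 on the 3 IGF1R-caPI3K arrays and 214, 125 and 194 on the IGF1R-dnPI3K arrays.

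**Figure D3:**
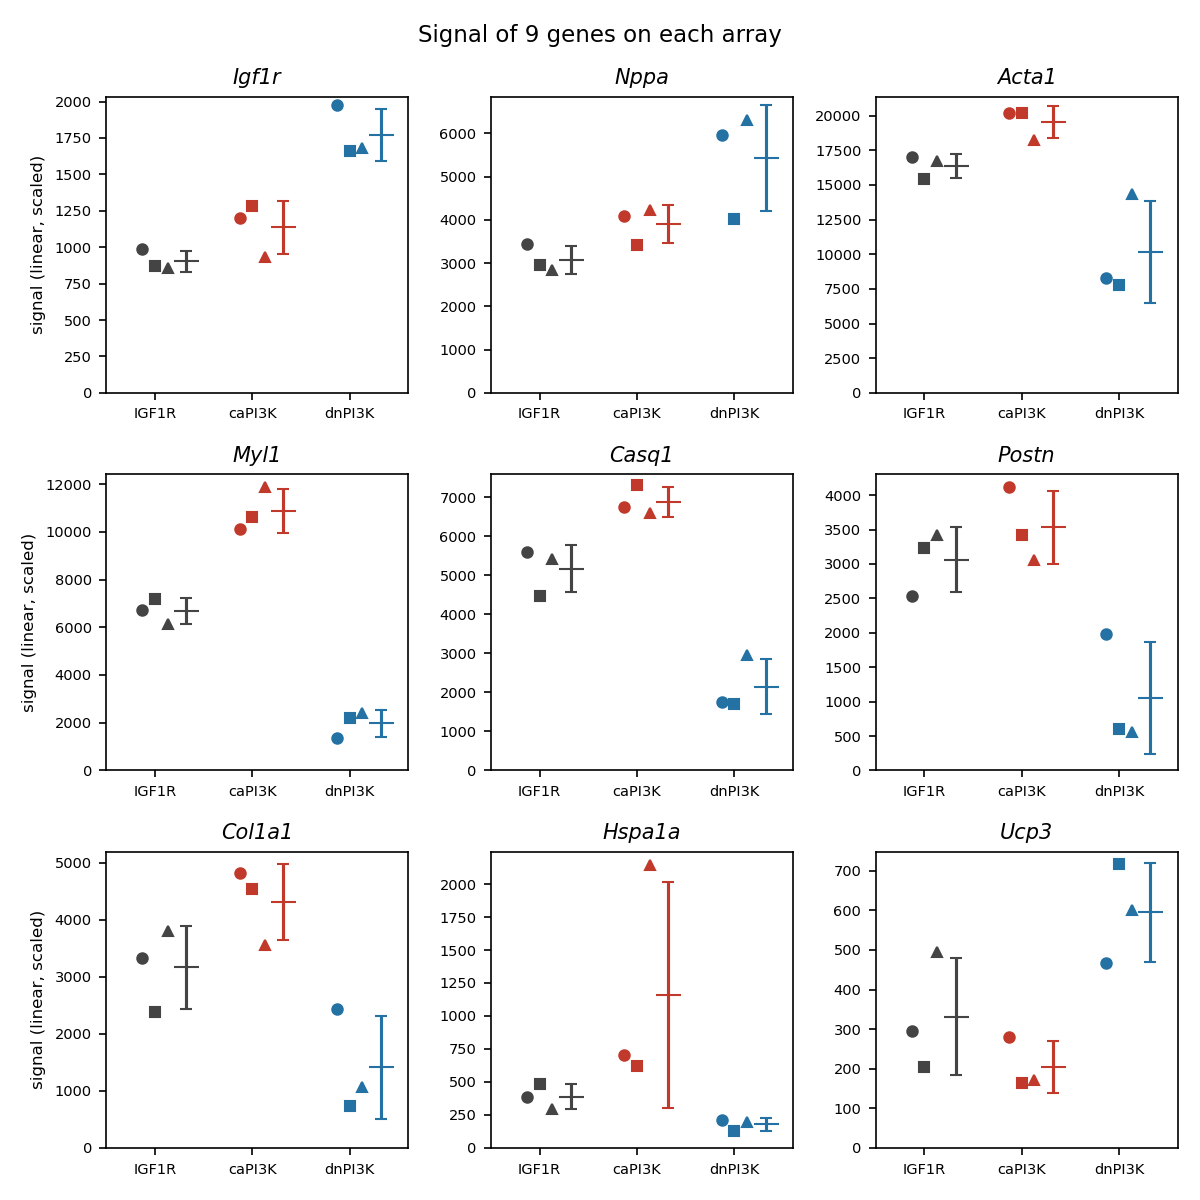
Deposited signal (vertical axis, linear scaled units) of 9 genes in IGF1R, IGF1R-caPI3K and IGF1R-dnPI3K mice; symbols are the 3 arrays of a group (circle, square and triangle for replicates 1, 2 and 3), and the bar to their right gives the mean and SD. Myl1 lies at 10870 in IGF1R-caPI3K and 1985 in IGF1R-dnPI3K mice on average, and the IGF1R-dnPI3K mean of Postn (1047) rests on 1 mouse at 1988 and 2 at 601 and 552.

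Further genes higher with active PI3K were Qsox1 (1.64 ± 0.30), Srpx (1.63 ± 0.34), Itga5 (1.51 ± 0.27) and Serpinf1 (1.43 ± 0.14, adjusted p = 9.88e-04). The other probe sets of Qsox1 and Serpinf1 differed by 0.0215 and 0.0525. The size for Srpx is open here too (0.69 to 2.10 over the alternatives). Lower with active PI3K were the same Tbc1d10a probe set (-3.08 ± 0.24, adjusted p = 1.64e-04; the other at 0.18 ± 0.70), the mitochondrial uncoupling protein gene Ucp3 (-1.56 ± 0.32), the enkephalin precursor Penk (-1.49 ± 0.26), the coagulation inhibitor Tfpi (-1.40 ± 0.14, adjusted p = 0.00103) and Cd79a (-1.37 ± 0.22). The carbonic anhydrase Car14 (-1.33 ± 0.24), Ces1d (-1.28 ± 0.16), Ifitm2 (-1.23 ± 0.26), Gnb3 (-1.18 ± 0.19), Apbb1 (-1.15 ± 0.23) and Selenbp1 (-1.04 ± 0.18) were lower as well, as was the dimmer probe set of Arhgap9 (14.8 ± 3.87 against 236 ± 76.6). With 1 group at background and a difference of open size, the amino acid transporter Slc7a7 was higher (163 ± 8.31 against 33.0 ± 17.9) and Tpd52l1 lower (45.4 ± 28.1 against 179 ± 35.9) with active PI3K; neither passed with a floor at the 40th percentile. In antioxidant genes, Nqo1 (0.84 ± 0.17) and Hmox1 (0.59 ± 0.12) were higher and Gstm2 (-0.59 ± 0.12, its other probe set at -0.0671) and Ces1d lower, 2 of 24 each way (2 and 4 over the list alone).

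The matrix and fibroblast list lay higher with active PI3K (median 0.47, camera adjusted p = 4.89e-07): 5 of 32 rose and none fell (14 and 2 over the list alone). The heat shock list did so too (adjusted p = 7.98e-06; 3 of 14, or 7 over the list alone), as did myeloid markers (adjusted p = 2.10e-04; 0 of 16, or 7 over the list alone) and fetal and hypertrophy markers (adjusted p = 0.00703; 1 of 11, or 6 up and 1 down over the list alone). The fetal marker that passed was Acta1, 19528 ± 1137 against 10142 ± 3675, a difference of 1.00 ± 0.19 (adjusted p = 0.0368). Of the 11 fetal markers 9 lay higher and 2 lower with active PI3K. Nppa was among the lower ones, 3916 ± 439 against 5430 ± 1227, and did not pass. Fatty acid oxidation lay lower (median -0.28, adjusted p = 6.49e-08; median -0.20 after quantile normalization): Etfb (-0.68 ± 0.13, its other probe set at -0.0272), Ucp3 and Echs1 (-0.74 ± 0.15) fell, 3 of 22 (8 over the list alone). Oxidative phosphorylation lay lower with no gene passing over all genes tested (median -0.27, adjusted p = 9.76e-11; median -0.10 after quantile normalization; 8 of 45 over the list alone), as did adipocyte markers (median -0.58, adjusted p = 0.00111; 0 of 8, or 5 over the list alone). With an estimated correlation none passed: the adjusted p was 0.273 for matrix and heat shock genes, 0.427 for myeloid markers and 0.188 for the fetal, fatty acid oxidation, oxidative phosphorylation and adipocyte lists. None of these lists shifted in IGF1R-caPI3K against IGF1R mice. There the camera adjusted p was 0.0699 for fetal markers, 0.196 for fatty acid oxidation and 0.450 for oxidative phosphorylation. It was 0.479 for matrix, heat shock and adipocyte genes and 0.886 for myeloid markers.

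The other 4 lists that lay lower with active PI3K were the tricarboxylic acid cycle (adjusted p = 5.40e-05), ribosomal proteins (8.93e-04), FoxO targets (0.0144) and the sarcomere (0.0195). Of these, Idh2 (-0.77 ± 0.15), 1 of 17 cycle genes, and the proapoptotic gene Bcl2l11 (-0.92 ± 0.17, its other probe set at 0.519), 1 of 15 FoxO targets, fell; no ribosomal or sarcomere gene did. Over the list alone, 1 cycle gene, 1 sarcomere gene and 2 FoxO targets fell, and 1 FoxO target rose. With an estimated correlation the adjusted p was 0.188 for the cycle, 0.427 for ribosomal proteins and FoxO targets and 0.563 for the sarcomere. In IGF1R-caPI3K against IGF1R mice ribosomal proteins lay higher (camera adjusted p = 0.0322). The cycle (0.886), FoxO targets (0.886) and the sarcomere (0.26) did not shift there. After quantile normalization none of the 4 passed: the median moved from -0.16 to -0.03 for the cycle, from -0.21 to -0.04 for ribosomal proteins and from -0.13 to 0.00487 for the sarcomere, whose direction turned, but only from -0.27 to -0.20 for FoxO targets. In the proteasome list Psme1 fell, 1 of 30 (1 over the list alone), by 0.65 ± 0.11 on the log2 scale (adjusted p = 0.0204).

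In total, 98 of 7898 probe sets differed between these groups, 58 higher with active PI3K and 40 lower, and the groups did not overlap in 19.5% of probe sets, against 10% by chance. Without 1 array the count was 64, 65 or 51 (IGF1R arrays), 10, 10 or 22 (IGF1R-caPI3K arrays) and 537, 18 or 63 (IGF1R-dnPI3K arrays). It was 13 with only the 6 arrays in the fit, all of them among the 98. With the mouse number series as a block this comparison, too, rests on IGF1R-dnPI3K replicate 1.

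Across all 3 groups, 572 probe sets differed in the limma F test. Without 1 array the count was 63, 91 or 48 (IGF1R arrays), 100, 76 or 123 (IGF1R-caPI3K arrays), 1533 (IGF1R-dnPI3K replicate 1) and 373 (IGF1R-dnPI3K replicate 2) for probe sets changed, any of the 3 groups. The fold changes of the 2 PI3K transgenes against the same IGF1R arrays correlated across probe sets, which are not independent replicates, with r = 0.632, against 0.4999 in simulated unchanged groups sharing those arrays. Their covariance was 0.114, against 0.0375 in a second set of simulations. That set was drawn from the residual variances, while the simulated r came from the moderated ones. Of the 12 probe sets that rose with active PI3K, 9 also rose with dominant negative PI3K. Independent lists would share 0.684, and lists of these sizes with the lowest p in 100 simulations of unchanged groups sharing the IGF1R arrays shared 7.18 on average and at most 12. Of the 5 that fell, 2 also fell, against 0.39 and 3.62. The simulations gave all 3 groups the same spread. The real IGF1R arrays spread less than the IGF1R-dnPI3K arrays (median SD of log2 signal 0.16 against 0.26). The simulated overlaps therefore cannot decide whether the real ones exceed what the shared arrays give. No probe set passed in both comparisons in the simulations. With 3 IGF1R arrays these could not be split into parts of at least 2, so part of the correlation may come from the shared arrays.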

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

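The tests of the covariance, the control signals and Gapdh, the signal-matched lists, the fibroblast markers and the differences within a mouse number series were chosen after the result was seen, as was the use of alternatives fixed earlier (quantile normalization, only the groups compared, an array left out) to weigh explanations; the counts over other splits were chosen before.

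Signal outside the tests separated the IGF1R arrays from the rest. The CreX control ratio averaged 1.18 on the 3 IGF1R arrays and 1.81 on the other 6 (exact permutation test, two-sided p = 0.0119, the smallest that 84 splits can give). Of 9 hybridisation control probe sets, 4 were higher on each IGF1R array than on any other array. Of 4 ratios of 3' to 5' signal from the RNA of the sample, that of Gapdh also separated them (mean 0.774 against 0.878; exact permutation test, two-sided p = 0.0119, adjusted p = 0.0476), and those of Actb, pyruvate carboxylase and the transferrin receptor did not. The Actb ratio did separate the PI3K groups from each other (at most 1.04 in IGF1R-caPI3K and at least 1.09 in IGF1R-dnPI3K).

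A separate hybridisation or scan of the IGF1R arrays is a candidate explanation of changes shared by both PI3K groups. The covariance of the 2 fold changes exceeded that of simulated unchanged groups by 0.0766. Such a difference, a difference in the RNA or its labelling, or a shared effect of a second transgene would give that. The design holds no IGF1R array processed like the others, so these cannot be told apart. A separate hybridisation or scan of the IGF1R arrays does not account for differences between the PI3K groups, whose fold changes do not use those arrays. Leaving those arrays out changed only the estimate of spread, and 13 probe sets then passed instead of 98. A trend with signal between arrays is a candidate explanation of part of the shift of the 6 lists higher in IGF1R-dnPI3K than in IGF1R mice. After quantile normalization 6 of the 6 lost their call, with medians moving from 0.27 (quartiles 0.06 and 0.61) to 0.07 (-0.10 and 0.27) for oxidative phosphorylation and from 0.35 to 0.08 for ribosomal proteins, but only from 0.18 (-0.02 and 0.29) to 0.14 (-0.11 and 0.33) for the proteasome, whose median log2 signal of 11.10 lay below that of the lower heat shock list (11.59). Among 10000 random lists matched on signal, the medians lay at the percentile 99.04 for ribosomal proteins, 97.1 for the sarcomere, 96.1 for oxidative phosphorylation, 84.6 for the proteasome, 82.3 for the tricarboxylic acid cycle and 76.2 for fatty acid oxidation, which leaves a trend as the whole cause open, since random lists lack the correlation of genes within a list.

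The low count of IGF1R-caPI3K against IGF1R was weighed next. A candidate explanation is the spread of the IGF1R-dnPI3K arrays in the shared estimate: with only the other 6 arrays in the fit, 699 probe sets passed (310 higher, 389 lower) instead of 17 (12 and 5). Much of that may come from IGF1R-dnPI3K replicate 3, without which 549 passed. Neither count says that the changes follow from PI3K, since the CreX difference between the groups remains, and no biological explanation was tested.

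The lower matrix genes of IGF1R-dnPI3K mice were weighed last. IGF1R-dnPI3K replicate 3 is not the whole cause, since without it the list kept its difference between the PI3K groups (camera adjusted p = 5.07e-07; 4.89e-07 with it; 3.05e-09 to 0.273 over all alternatives). A smaller share of fibroblasts would lower matrix genes and other fibroblast markers alike. The 16 collagen and matrix genes differed by a median of 0.92 (from Col1a2 at 0.02 to Postn at 2.01) and the 9 other fibroblast markers by 0.13. Both ways occurred among the latter: Timp3 was at -0.95, Dpt at -0.45, Dcn and Pdgfra at 0.13, Bgn at 0.44, Mgp at 0.48 and Lum at 1.03. The means differed by 0.838 (permutation test over genes, two-sided p = 0.00274, or 0.00839 without Timp3, the highest with 1 marker left out). Matrix genes thus differed more than these markers. The test takes genes as independent and does not measure the spread between mice. Lum, a marker here, was named above among the matrix genes, and the genes were divided after the data were seen. A smaller share of fibroblasts therefore stays open. The mouse number series stays open: replicates 2 and 3, from a series of their own, had list medians of -0.65 and -0.64 against the IGF1R-caPI3K mean and replicate 1 had -0.29; against the IGF1R mean they had -0.57 and -0.60 and replicate 1 had -0.15. Within the series that starts with 10, the median was -0.313 against the IGF1R-caPI3K mouse and -0.425 against the IGF1R mouse, with 1 mouse each: on both sides of 0.341, the largest difference between 2 arrays of the IGF1R or of the IGF1R-caPI3K group, and within 0.438, that of the IGF1R-dnPI3K group, whose mice come from 2 series. An effect of dominant negative PI3K remains a hypothesis.

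A further pick was made among genes that the fixed rule named for the PI3K groups and that passed there in limma, each on its brightest probe set. It took those where all IGF1R-caPI3K arrays lay on one side of all IGF1R arrays and all IGF1R-dnPI3K arrays on the other. Other passing genes were not searched, so the pick is drawn mainly from the largest differences. Higher with active PI3K were Hspa1a (2.50), Myl1 (2.49), Casq1 (1.73), Qsox1 (1.64) and Acta1 (1.00), as log2 differences. Lower with active PI3K were Tfpi (-1.40), Ces1d (-1.28) and Ifitm2 (-1.23). Slc7a7 was also higher and Tpd52l1 lower, but 1 group was at background, so their fitted differences of 2.09 and -2.02 depend on the floor and their sizes are open.

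Other splits of the samples were counted. For the F test over the 3 groups, 1 of 100 splits, the real one, gave as many as 572 probe sets and the highest other gave 30, so chance splits can be excluded there. The 6 arrays of a pairwise comparison have 10 splits, too few for a share under 0.05. The real and highest other counts of probe sets were 17 and 0 for IGF1R-caPI3K against IGF1R, 1066 and 0 for IGF1R-dnPI3K against IGF1R, and 98 and 1 between the PI3K groups, with 1 of 10 splits as large in each. For gene lists they were 2 and 9 (8 of 10 splits as large), 9 and 13 (3 of 10) and 11 and 13 (3 of 10). In each comparison other splits thus shifted as many lists, so the list counts do not set the real groups apart.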

How the results depend on the processing

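The alternatives without shared-target probe sets and those that combine quantile normalization with other arrays were chosen after seeing the data. No paired analysis was possible because the titles give mouse numbers that no 2 groups share. Unless a cause is named, the cause was not tested. Main counts were 17 (IGF1R-caPI3K against IGF1R), 1066 (IGF1R-dnPI3K against IGF1R), 98 (between the PI3K groups) and 572 (any group), and 2, 9 and 11 lists. The first count, in alternatives that moved it, was 78 with quantile normalization (45 higher and 33 lower, against 12 and 5), 3 with a common median, 67 with a floor at the 40th percentile, 0 with no filter (more probe sets tested; 1766 with an unadjusted p under 0.05), 59 with a filter at the 60th percentile, 7 without the variance trend, 777 with array weights, 1 with the number series as a block, 3 without shared-target probe sets, 4 with only mice numbered from 14, 699 with only the 2 groups, 650 with these quantile normalized, and 526 quantile normalized without IGF1R-dnPI3K replicate 3. The second was 387 with no filter, 657 without the trend, 132 with 2 groups, 319 with these quantile normalized and 492 quantile normalized without IGF1R-dnPI3K replicate 3. The third was 36 with no filter, 45 without the trend, 348 with array weights, 13 with 2 groups and 35 with these quantile normalized. The count of probe sets changed, any of the 3 groups, was 158 with no filter, 137 without the trend and 1633 with array weights. The block leaves 1 IGF1R-dnPI3K mouse to compare, so its counts are not given for these 3. With 1 array left out the counts ranged from 0 to 549, 77 to 1856, 10 to 537 and 48 to 1533, and lists from 0 to 4, 7 to 10 and 10 to 13. Lists for the first comparison were 0 with an estimated correlation, with fry, with the mean of a gene's probe sets, with a common median, with the higher floor and with the higher filter, 4 with array weights and 1 quantile normalized with 2 groups. For the second they were 0 with an estimated correlation, 5 with fry, 3 with quantile normalization, 2 without IGF1R-dnPI3K replicate 3 as well and 3 with 2 groups as well. For the third they were 0 with an estimated correlation and 7 with quantile normalization. The correlation of fold changes, 0.632, was 0.514 with the block and 0.579 to 0.670 with 1 array left out.

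Directions turned for the sarcomere, IGF1R-dnPI3K against IGF1R (adjusted p = 0.636 quantile normalized, 0.613 without IGF1R-dnPI3K replicate 3 as well, 0.634 with 2 groups as well; 0.00108 to 0.636 over all alternatives) and the sarcomere, IGF1R-caPI3K against IGF1R-dnPI3K (0.977 quantile normalized, 0.949 with 2 groups as well; 0.00384 to 0.980 over all). They turned for myeloid markers of IGF1R-dnPI3K against IGF1R with the block (0.995; 4.49e-04 to 0.995 over all). Quantile normalized, Myl3, IGF1R-dnPI3K against IGF1R, was -0.0384 with all groups or 2. Myh6, IGF1R-dnPI3K against IGF1R, was -0.0658 in both and -0.00914 without IGF1R-dnPI3K replicate 3, and -0.18 in IGF1R-caPI3K against IGF1R quantile normalized with 2 groups. Of 144 named calls, quantile normalization kept 125, the block 5 and no filter 41; of 22 list calls the block kept 13, lost 8 and turned 1; of 143, leaving out IGF1R replicate 3 kept 27. Of 27 alternatives, lists between the PI3K groups passed in 26 (matrix, heat shock, oxidative phosphorylation, fatty acid oxidation and adipocyte, all but the estimated correlation), 25 (fetal), 24 (tricarboxylic acid cycle, myeloid), 21 (ribosomal), 20 (FoxO) and 17 (sarcomere). Lists of IGF1R-dnPI3K against IGF1R passed in 25 (matrix), 23 (heat shock, oxidative phosphorylation, ribosomal, proteasome), 22 (tricarboxylic acid cycle), 21 (sarcomere, myeloid) and 17 (fatty acid oxidation). For IGF1R-caPI3K against IGF1R it was 15 (cell cycle) and 16 (ribosomal) of 28.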

Other observations

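Smooth muscle and pericyte markers had a median log2 difference of 0.19 in IGF1R-dnPI3K against IGF1R mice (camera adjusted p = 0.0968), and none of 10 passed. Genes of the circadian clock did not shift as a list (adjusted p = 0.647), while Clock (-0.82 ± 0.20) and Bhlhe40 (-1.23 ± 0.31), 2 of 12, were lower in IGF1R-dnPI3K mice. Changes went both ways among antioxidant genes in the same comparison, with 5 of 24 higher, Gstm1 (0.61 ± 0.14) among them, and 6 lower, among them Sod1 (-0.67 ± 0.13) and Txnrd1 (-0.70 ± 0.18). The mean signal of Sod1 was alike in IGF1R-caPI3K (2041) and IGF1R-dnPI3K mice (1971). The atrial markers, which include Nppa, gave no shift (adjusted p = 0.903), and Myl4 (-0.69 ± 0.21) did not pass. Translation factors did not shift either (adjusted p = 0.807): Eef1a1 was higher (0.53 ± 0.12) and the initiation factor genes Eif3a (-0.95 ± 0.19) and Eif3e (-0.99 ± 0.22) lower. The means of IGF1R-caPI3K and IGF1R-dnPI3K mice lay near each other for Eif3a (824 and 737) and Eif3e (467 and 400). Lipe, the hormone-sensitive lipase, was higher by 1.26 ± 0.25 in IGF1R-dnPI3K mice, 1 of 8 adipocyte markers, a list that shifted only between the PI3K groups. Interferon response and antigen presentation genes had no passing member in any of the 3 comparisons.

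The lists not yet named shifted in none of the 3 comparisons. For the genes of PI3K and its receptors the camera adjusted p in IGF1R-caPI3K against IGF1R, IGF1R-dnPI3K against IGF1R and between the PI3K groups was 0.629, 0.0968 and 0.0648, with Igf1r as the 1 of 8 that passed. For glycolysis it was 0.597, 0.211 and 0.309, and 2 of 16 genes, Aldoa (0.59) and Eno3 (0.49), were higher in IGF1R-dnPI3K than in IGF1R mice; another probe set of Aldoa differed by -0.36. For cardiac transcription factors it was 0.845, 0.262 and 0.283, and Gata6 (0.85) and Esrra (0.51), 2 of 15, were higher in IGF1R-dnPI3K mice; another probe set of Esrra differed by -0.00274. For immediate early genes it was 0.886, 0.554 and 0.217; Gadd45b was higher and Ier2 (-0.64) and Ccn1 (-0.63) lower in IGF1R-dnPI3K mice, 3 of 16. For angiogenesis and hypoxia it was 0.479, 0.647 and 0.842, with Hmox1 as the 1 of 16 that passed, and for lymphocyte markers 0.886, 0.736 and 0.437. Of 4 red blood cell genes, too few to test as a list, none passed.

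The genes of this paragraph were chosen after their values were seen. Within the IGF1R-dnPI3K group the signal of Ptgds was 3295, 7875 and 13380 in replicates 1, 2 and 3. Acot1 was at 390, 1227 and 1134, and Rcan1 at 4397, 1588 and 1512. Myh7, beta-myosin heavy chain, ranged from 12904 to 34746 in this group and passed in no comparison.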
